A study of Rattus norvegicus with 24 samples.

How the data were processed

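The series holds 24 two-colour Agilent arrays of rat dorsal root ganglia from segments given in the labels, in 8 groups of 3: sciatic nerve crush (SN) or dorsal root crush (DR) at 12h, 24h, 72h or 7d. Per the labels, Cy5 carries RNA of lesioned ganglia on every array and Cy3 a common reference, and the design text describes 3 biological replicates per time and a reference pooled from 3 unlesioned animals. There is no dye swap, so a dye bias stays in each comparison with the unlesioned pool. Between SN and DR it cancels only as far as it is equal on the arrays of both lesions, which differ in Cy5 brightness and spike-in slope. A ratio tested against 0 leaves out the spread between unlesioned animals, since none has an array of its own. Groups were taken from the sample titles.

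Spot intensities are mean pixel brightness with a local background median for each channel, per the file headers, written by Feature Extraction 8.1.1.1. The log10 ratios in the same files are red over green processed signals, background-subtracted and dye-normalized by that program, per the file headers. The deposited series table holds log2 ratios of lesioned over unlesioned normalized within arrays by the authors, with limma named in the submitters' processing notes. Its background and normalization steps and the limma version are not given in the sources used here. Columns of that table were matched to arrays from their values: each correlated best with its own array (r 0.971 to 0.997). Their slope on the log2 ratios used here was 1.08 to 1.22, near that of a log2 scale. Flags of 0 or 1 per spot (other values) mark outliers, saturation and signal above background, per the file headers.

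From each array mean signals and background medians were corrected with normexp (offset 50), and log2 ratios were normalized within arrays by loess with control spots at weight 0. Of 43628 spots 2256 are controls and were left out, outlier spots (9 to 367 per array) were set to missing, and 40 probes printed 10 times were averaged, leaving 41012 probes. No normalization between arrays was applied to these ratios (lower-bound folds, described below, use Aquantile). A probe was kept if it was well above background in Cy5 on all 3 arrays of at least 1 group, or in Cy3 on at least 12 of the 24 arrays, which 25471 probes were. The probe with the highest mean brightness stood for each gene, giving 22188 genes or accessions, 11735 with a symbol of their own. Of the 532512 values tested, 784 were missing. Where a gene had more than 1 probe (2490 genes, 1354 of them called between SN and DR), another probe was called in the opposite direction for 173.

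Symbols were matched through the supplied reference table by accession (10691 probes), gene ID (497), symbol (4645), synonym (3879) or description (1335), while 19965 probes kept the name in the file. Crisp3 bears the name Crisp1 in the array file, and Or8g28c-ps1 the name Olr1299-ps.

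Signal sets the precision of arrays. Net Cy5 brightness averaged 183 to 495.6 per SN array and 499 to 938.6 per DR array, against 385.1 to 583.6 and 333.3 to 527.7 in Cy3. The spike-in slope is negative in the header of every array (−1.024 to −0.869). Its size was 0.869 to 0.917 on SN arrays (correlation 0.909 to 0.928) and 0.965 to 1.02 on DR arrays (0.990 to 0.994). The mean correlation of log ratios within groups was 0.448, 0.563, 0.787 and 0.733 for SN and 0.480, 0.621, 0.664 and 0.529 for DR, in order of time. Scan days follow from the file headers: SN at 12h and 24h share a day, SN at 72h and 7d share another, DR at 12h, 24h and 72h share another, and DR at 7d has its own.

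Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 24 arrays, and moderated by eBayes. Each group was tested against 0 (the unlesioned pool), SN against DR at each time and in the mean of the 4 times by moderated t, and time within each lesion and lesion by time by moderated F. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg, per comparison). For a probe not well above background or saturated on every array of a group, the fold is a lower bound from channel values after loess and Aquantile, open to dye bias, or is left out. Lists of genes were tested with camera (preset correlation 0.01, with an estimated correlation as an alternative), adjusted over 35 lists with at least 5 measured members. The adipocyte list, with 3 of 9 members measured, was not tested. Names were matched in Python 3.11.15.

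Lists, comparisons, the rule for naming genes and all alternatives but the 3 given below as added were fixed before the data were examined. The rule names genes with a symbol of their own: the 12 called with the largest rise and the 12 with the largest fall in the mean of SN and DR with the same sign at all 4 times, the 5 and 5 largest in each other comparison, the 8 smallest F-test p-values of each time test, up to 4 called members of each list, and 22 genes given beforehand. The genes given include Atf3, Jun, Sprr1a, Gap43, Sox11, Gal, Npy, Vip, Adcyap1, Gadd45a, Stat3, Socs3, Nfil3, Smad1, Calca, Tac1, Scn10a, P2rx3, Nefh, Gfap and Aif1, and some named genes are not reported here.

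The tests were tried on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale in arrays of the same spread. The share recovered at the smaller change was 91, 89, 95 and 90 percent for SN against the pool in order of time, 98, 94, 92 and 89 for DR, 81, 73, 76 and 73 for SN against DR, 99 for their mean, 78 and 75 for time in SN and DR, and 32 for the interaction. At the larger change it was 92 percent for the interaction and 96 to 100 for the others. False calls were 3.55 to 6.9 percent of calls, and a list shifted by 0.3 was called with 0 of the lists sharing no gene with it. The simulated noise was independent between genes and held no shift by scan day or brightness. These rates therefore do not cover correlated genes, on which camera depends, or such shifts.

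Alternatives were Agilent's own log ratios, no background subtraction, median centring in place of loess, no filter (36225 genes), only probes well above background in both channels on all arrays (10475 genes), the deposited series table, eBayes with trend and robust, the mean of all probes of a gene, a block for replicate number, the 6 compared arrays alone, scan day as a block within days or as a random block, and each array left out in turn. Array weights, division by the size of the spike-in slope and the fit without the 12h groups were added after seeing the data. Camera was not run with the random block or with trend and robust. Genomic positions were not used, as no genome build is given in the sources used here.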

Results

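Rat dorsal root ganglia were profiled after crush of the sciatic nerve, which cuts the peripheral branch of the sensory axon (SN), or of the dorsal root, which cuts its central branch (DR). Ganglia were taken at 12h, 24h, 72h and 7d, with 3 arrays per lesion and time, and every array was hybridized against the same pool from 3 unlesioned animals. All adjusted p-values for single genes are from limma and those for gene lists from camera. The number of arrays limits the precision of each value, and no lesion shares a scan day with the other, so levels in SN and DR cannot be told apart from differences between scan days, and only changes within a scan day can be compared free of a constant shift.

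**Figure D1:**
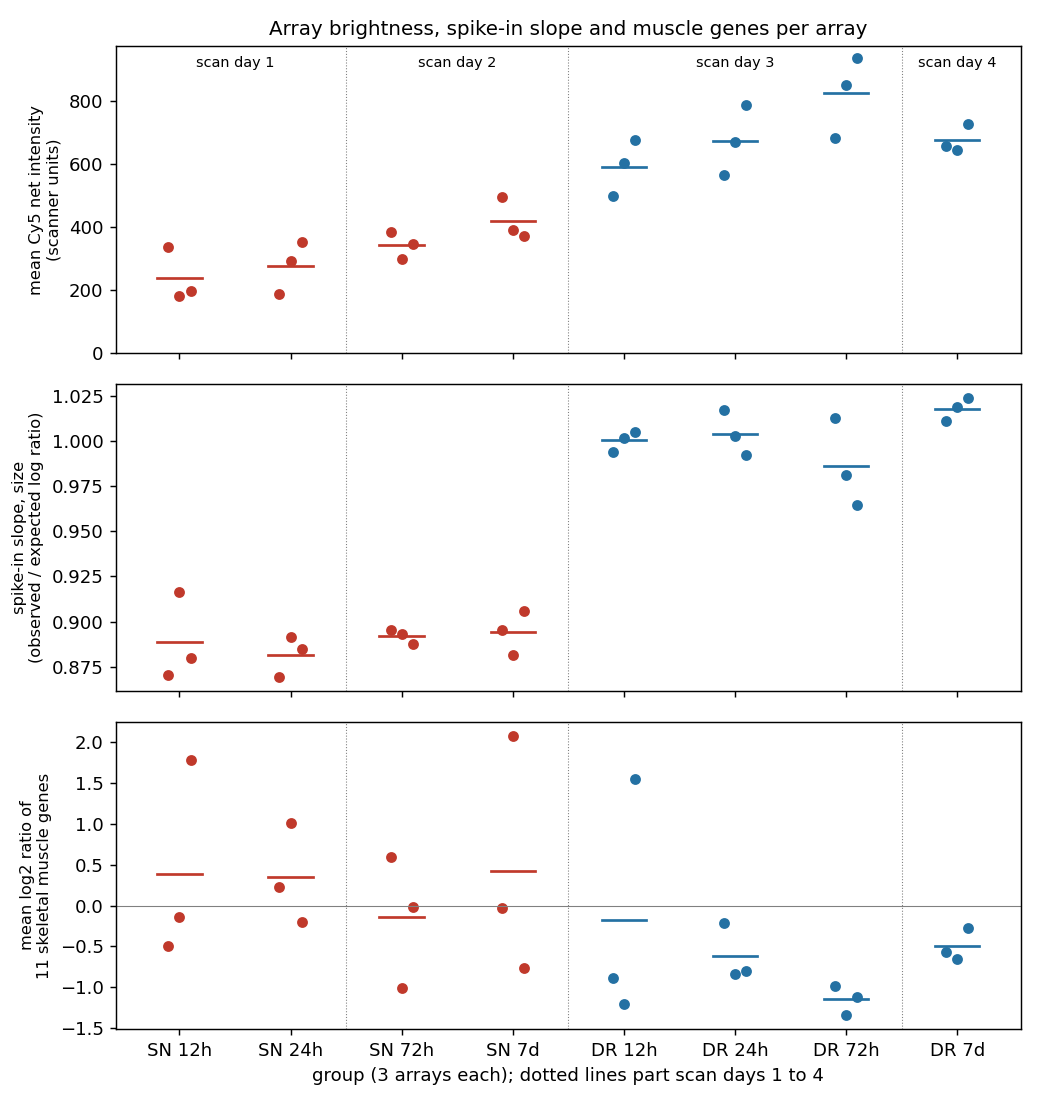
Arrays by scan day and lesion. Each scan day holds arrays of a single lesion.

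Crisp3, the muscle LIM protein gene Csrp3 and the neuropeptide genes Vip and Gal were far above their DR levels after nerve crush. Averaged over the 4 times, Csrp3 was 6.77-fold higher in SN than in DR (log2 2.76, SE 0.077, adjusted p = 9.62e-16) and Gal 3.83-fold (log2 1.94, SE 0.12, adjusted p = 5.38e-10), with 12 arrays per lesion. No size is given for Crisp3 (adjusted p = 3.3e-18), well above background on 9 of 12 SN and 3 of 12 DR arrays, or for Vip (adjusted p = 1.78e-15), on 9 of 12 in each lesion and none at SN 12h. For each of these genes 9 of the 12 SN arrays lay above every DR array. Vasoactive intestinal peptide and galanin are classical peptides of injured sensory neurons. The cell adhesion gene Flrt3 (log2 1.38, adjusted p = 4.93e-09), the potassium channel gene Kcnd3 (log2 1.36, adjusted p = 5.55e-11), Ankrd1 (adjusted p = 1.04e-10) and Cd44, the hyaluronan receptor gene (log2 1.36, SE 0.10, adjusted p = 6.06e-09), were also higher in SN. Ankrd1 was well above background on 9 of 12 SN arrays, none of them at 12h, and on 8 of 12 DR arrays. With Agilent's own ratios Kcnd3 (2.59) differed more widely. Cd44 was above every DR array on all 12 SN arrays, which a constant shift between scan days could also give. Under median centring, which lowers the median of the tested genes to −0.44, Csrp3 (2.38) changed little, while Gal fell to 0.84, Flrt3 to 0.38 and Cd44 to 0.30. The probe of Nefm, a neurofilament gene (adjusted p = 2.83e-08), was saturated on every array of 7 of the 8 groups, so no fold or direction is taken from it. The fast muscle genes Tnnc2 (log2 1.93, SE 0.61, adjusted p = 0.0134), Myl11 (log2 1.60, SE 0.56, adjusted p = 0.0222) and Tnni2 (log2 1.52, SE 0.53, adjusted p = 0.0238) differed as widely on average, but only 2 of the 12 SN arrays lay above every DR array, and none was called under median centring.

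Genes lower in SN than in DR included Shisa4 (log2 −1.49, SE 0.11, adjusted p = 2.36e-09), the saposin gene Psap (log2 −1.49, SE 0.11, adjusted p = 6.81e-09), Zfhx3 (log2 −1.17, SE 0.086, adjusted p = 2.91e-09) and Rgs3 (log2 −1.15, SE 0.052, adjusted p = 3.23e-12). Each of these 4 was below every DR array on all 12 SN arrays. Since each scan day holds a single lesion, this separation cannot be told apart from a constant shift between scan days. Under median centring, which moves genes this way, they were −2.53, −2.64, −2.19 and −2.15. None of them passed the test of lesion by time, nor did Cdkn2a, also lower in SN (log2 −1.11, interaction adjusted p = 0.0705). Tpm3 was lower on its brightest probe (log2 −1.26), while its 6 probes spread from −1.26 to 0.68.

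Among genes named beforehand as markers of axon injury, Gadd45a (log2 1.36, adjusted p = 1.56e-08), Sprr1a (adjusted p = 5.97e-10), Atf3 (log2 0.98, adjusted p = 0.000583), Npy (log2 0.96, adjusted p = 4.84e-06), Gap43 (log2 0.65, adjusted p = 2.84e-06), Smad1 (log2 0.47, adjusted p = 5.82e-06) and Adcyap1 (log2 0.32, adjusted p = 0.00319) were higher in SN. Sprr1a was well above background on 8 of 12 SN and 3 of 12 DR arrays, so no size is given. The mean of the Smad1 probes was 0.18, and they ran from −0.11 to 0.47. Among these genes Atf3 and Smad1 encode transcription factors, Npy and Adcyap1 neuropeptides and Gap43 a growth cone protein. Under median centring Atf3 turned to −0.028 (adjusted p = 0.915), Gap43 to −0.52, Smad1 to −0.43 and Adcyap1 to −0.67, and Gadd45a (0.31, adjusted p = 0.123) and Npy (0.084, adjusted p = 0.637) lost the call. Nfil3 (log2 0.18, adjusted p = 0.000865) and Socs3 (adjusted p = 0.00242) were called higher, but Nfil3 lost the call under median centring (0.013, adjusted p = 0.803) and Socs3 was well above background on only 1 of 12 SN arrays, whereas Sox11 (adjusted p = 0.267), Jun (adjusted p = 0.301), Gfap (adjusted p = 0.405) and Nefh (adjusted p = 0.1) did not pass. With Agilent's own ratios Sox11 (adjusted p = 0.0393) and Nefh (−0.31, adjusted p = 0.045) passed, and under median centring Sox11 (adjusted p = 0.0126), Jun (−1.21, adjusted p = 1.64e-06) and Nefh (−1.44, adjusted p = 6.65e-08). Sox11 was well above background on 4 of 12 SN and 9 of 12 DR arrays, and Gfap on 3 and 9. Their results thus do not measure absence of a difference. Stat3 was higher by its brightest probe (log2 0.27, adjusted p = 0.00441), but another of its probes gave −0.60 and the mean of its probes gave −0.17. Sensory genes were lower in SN: P2rx3 (log2 −0.95, SE 0.076, adjusted p = 9.37e-09), Calca (log2 −0.58, SE 0.083, adjusted p = 9.72e-06), Scn10a (log2 −0.42, adjusted p = 0.000164) and, less firmly, Tac1 (log2 −0.23, adjusted p = 0.0304), which lost the call in 6 of 24 fits with 1 array left out, as without DR 72h replicate 3 (adjusted p = 0.0611). The 3 Calca probes ran from −0.58 to 0.017, with a mean of −0.31, and the 2 P2rx3 probes gave −0.95 and −0.38. Under median centring, in the direction of its shift, these 4 genes were −1.93, −1.78, −1.52 and −1.40. The microglia and macrophage gene Aif1 was higher (log2 0.55, adjusted p = 0.000938), reversed to −0.50 under median centring.

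Over the 4 times together 10792 of 22188 genes differed between SN and DR, 4878 higher and 5914 lower in SN, but only 50 were at least 2-fold higher and 24 at least 2-fold lower. Differences were mostly small, with a median size of 0.22 on the log2 scale among the called genes. Replacing loess with median centring of each array, over all probes before the filter, brought the median of the tested genes from −0.017 to −0.44. It gave 3412 higher and 15028 lower. Against the pool this median was −0.073 to −0.22 in SN and 0.12 to 0.31 in DR under median centring. A change of sign in these directions thus mostly restates that shift. With lesion alone and scan day as a random block, 6843 were called, and Atf3 (log2 1.07, adjusted p = 0.0891), Gap43 (log2 0.62, adjusted p = 0.0698) and Npy (log2 0.88, adjusted p = 0.143) were no longer called. Nor were Adcyap1 (0.34, adjusted p = 0.386), Stat3 (0.23, 0.208), Nfil3 (0.19, 0.0689), Tac1 (−0.25, 0.185), Tnnc2 (1.90, 0.0509), Myl11 (1.56, 0.0797) and Tnni2 (1.56, 0.0688), their log2 values staying close to those above, nor Socs3 (adjusted p = 0.183). Each scan day holds a single lesion, and this fit counts arrays, not days, as replicates, with a correlation of 0.0904 within days. Its calls therefore do not separate lesion from scan day. The fit also leaves out time, so changes over time add to its spread. With lesion alone and no block 9526 genes were called. A call lost with the block thus need not come from scan day.

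Regeneration-associated genes as a group were higher after nerve crush than after root crush. Of 35 measured, 23 were higher and 2 lower in SN (23 and 2 adjusted over the list alone). The list passed camera (adjusted p = 2.42e-09, adjusted p = 0.0152 with an estimated correlation), with a median of 0.27. The median was 0.60 with Agilent's own ratios, 0.47 after division by the spike-in slope, 0.53 without the 12h groups and −0.13 under median centring, where the list still passed (adjusted p = 0.0278). Arg1, an enzyme gene linked to regrowth, was among its largest members (log2 1.39). Of 8 injury neuropeptide genes 4 were higher and 1 lower (4 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 0.0122, adjusted p = 0.528 with an estimated correlation), and the median became −0.096 under median centring, where the list did not pass (adjusted p = 0.114). Of 7 MHC class II genes, which mark antigen-presenting cells, 5 were higher and 0 lower (5 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 0.0131, adjusted p = 0.24 with an estimated correlation), but it did not pass under median centring (median −0.066, adjusted p = 0.114) or without the filter (11 genes, median 0.15, adjusted p = 0.0963). Cd74 (log2 0.86, SE 0.11, adjusted p = 2.44e-06) and RT1-Da (log2 0.86, SE 0.090, adjusted p = 2.49e-07) led this list, both above every DR array on 7 of 12 SN arrays, and under median centring they were −0.16 and −0.066. With scan day as a random block, which does not separate it from lesion, 17 regeneration-associated genes were higher and 1 lower. So were 2 and 1 of the neuropeptide genes, and 2 and 0 of the MHC class II genes.

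Nociceptor genes were lower in SN than in DR. Of 14 peptidergic nociceptor genes 10 were lower and 0 higher (10 and 0 adjusted over the list alone; median −0.40, camera adjusted p = 0.0122, adjusted p = 0.528 with an estimated correlation), among them Scn9a (log2 −0.71, SE 0.060, adjusted p = 1.61e-08), Trpv1 (log2 −0.62) and Calca. The 2 Scn9a probes gave −0.71 and −0.083. Of 13 non-peptidergic genes 11 were lower and 0 higher (11 and 0 adjusted over the list alone; median −0.27, camera adjusted p = 0.0016, adjusted p = 0.17 with an estimated correlation), including P2rx3, Sst (log2 −0.77) and Gfra2 (log2 −0.48). Under median centring, which lowers the median of all genes, these medians were −1.31 and −0.95. Against the other genes the peptidergic list no longer passed there (adjusted p = 0.114), while the non-peptidergic list did (adjusted p = 0.0471). With scan day as a random block, which does not separate it from lesion, 8 genes of each list were lower and 0 higher. Transient receptor potential and tetrodotoxin-resistant sodium channels carry noxious signals in these cells.

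**Figure D2:**
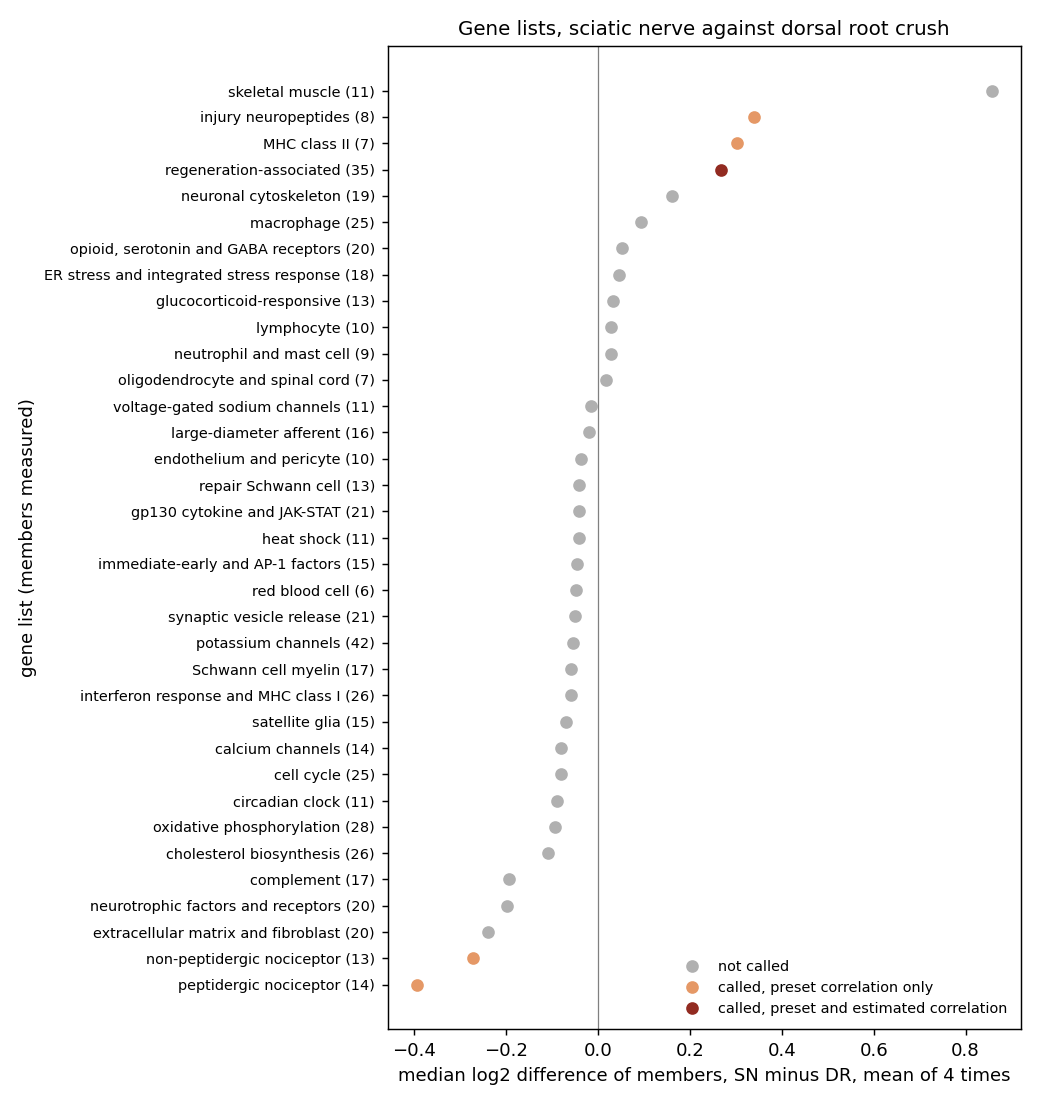
Gene lists in the comparison of SN with DR averaged over the times, by median log2 value and camera result. For the regeneration-associated, neuropeptide and MHC class II lists in the mean of SN and DR, the medians change sign under median centring, which lowers the median of all genes.

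For several genes higher in SN the time courses of the lesions parted after 12h, while some differences, as in Psap and Cd44, were present at 12h. Crisp3 stood at 0.026, 0.85, 5.33 and 5.06 over the 4 times after nerve crush (log2 against the unlesioned pool) and at 0.012, 0.035, −0.035 and 0.10 after root crush, but it was not well above background on any array at SN 12h or at DR 12h, 24h and 7d, so these values mark absence of signal. SN at 12h and 24h and SN at 72h and 7d were scanned on separate days. Vip rose from 0.073 at 12h, when no SN array had it well above background, to 4.31 at 7d in SN, against 0.014 and 0.33 in DR, and Gal from 0.54 to 3.15 against −0.028 and 0.53. Atf3 stood at 4.30, 4.26 and 4.35 from 24h on in SN, while in DR it was 2.92 at 12h and 1.81 at 7d. Lesion by time interaction was called for 1311 genes, with Crisp3 (adjusted p = 1.49e-15), Vip (adjusted p = 3.59e-10), Csrp3 (adjusted p = 7.47e-10), Gal (adjusted p = 0.00166) and Atf3 (adjusted p = 0.00368) among them. Of the 35 regeneration-associated genes 20 were called (28 adjusted over the list alone). So were 4 of 8 neuropeptide, 6 of 14 peptidergic nociceptor and 3 of 7 MHC class II genes (5, 8 and 4 adjusted over the list alone). Within scan days, where 12h and 24h can be compared, 783 genes changed differently between the lesions. Median centring called 72, with Crisp3 (adjusted p = 2.85e-11), Vip (adjusted p = 3.5e-06) and Csrp3 (adjusted p = 8.88e-06) among them but not Gal (adjusted p = 0.181) or Atf3 (adjusted p = 0.0627).

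**Figure D3:**
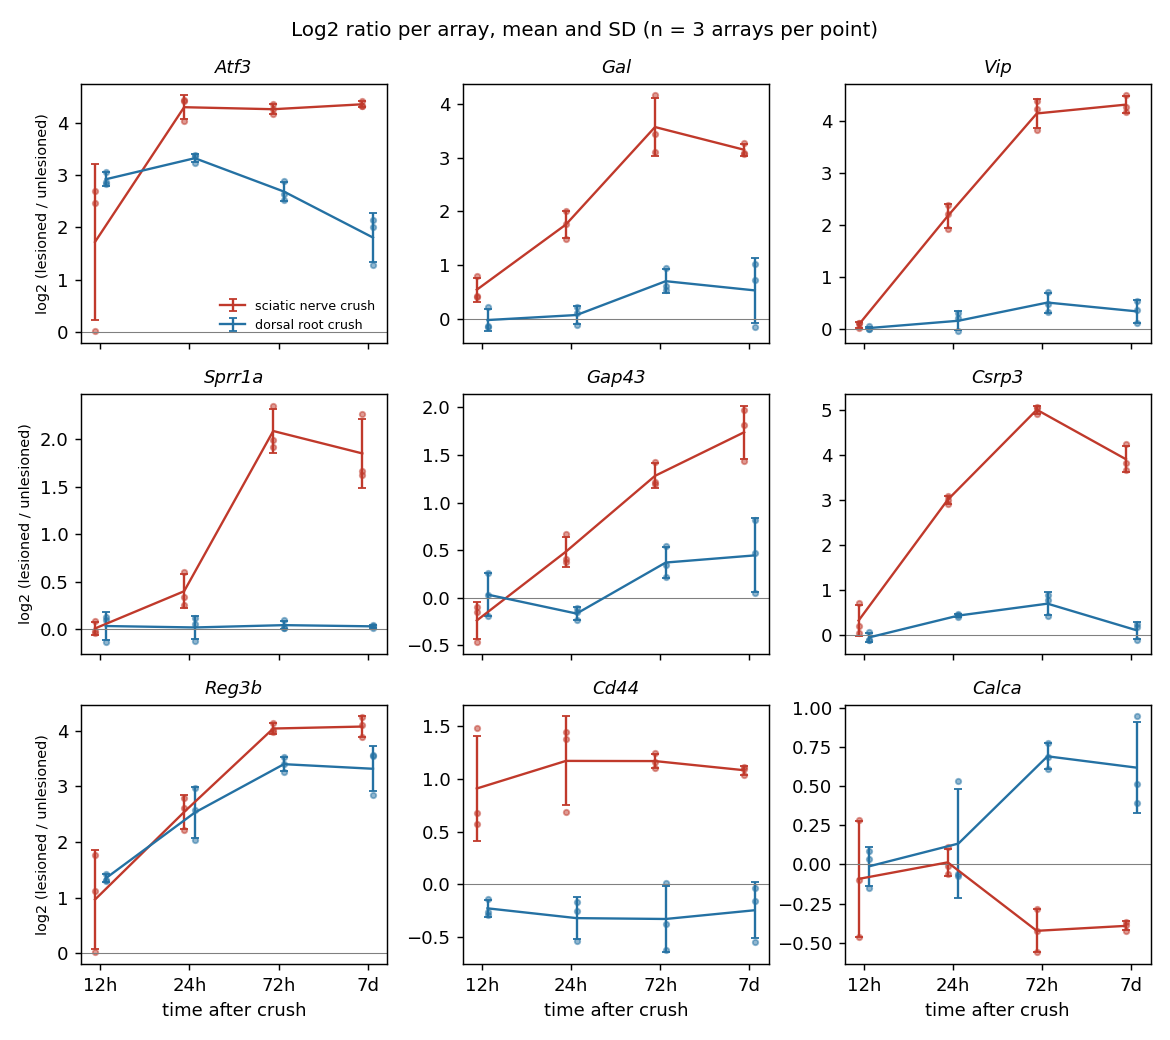
Log2 ratio to the unlesioned pool of selected genes on every array, by lesion and time.

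In SN alone, Crisp3 (adjusted p = 1.37e-18), Vip (adjusted p = 5.13e-14), Csrp3 (adjusted p = 1.02e-13), Serpina3n (adjusted p = 1.92e-12), the cytokine gene Il24 (adjusted p = 2.2e-12), the corticotropin family peptide gene Ucn (adjusted p = 2.2e-12) and Ptprh (adjusted p = 3.44e-12) changed most clearly over time. Over the 4 times 1665 genes changed, including 25 of 35 regeneration-associated genes (32 adjusted over the list alone), 13 of 25 macrophage genes (17) and 5 of 8 neuropeptide genes. Within scan days 409 changed by a joint F test. Each tested and adjusted alone, 700 differed between 24h and 12h, 551 higher and 149 lower at 24h, and 8 between 7d and 72h in limma (1081 at an unadjusted p under 0.05). Median centring called 382.

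In DR alone, the changes over time were led by Arhgef25 (adjusted p = 3.1e-06), Serpina3n (adjusted p = 2.6e-05), the clock output gene Dbp (adjusted p = 0.00024) and the early transcription factor gene Cebpd (adjusted p = 0.000252). Dbp stood at −0.44, 0.61, 0.094 and −0.26 over the 4 times. Over time 2019 genes changed, among them 7 of 35 regeneration-associated genes (14 adjusted over the list alone) and 7 of 25 cell cycle genes (13). Within the scan day that holds 12h, 24h and 72h, 1152 changed by a joint F test. Each tested and adjusted alone, 152 differed between 24h and 12h (79 higher, 73 lower) and 1018 between 72h and 12h (381 higher, 637 lower). The count was 645 with Agilent's own log ratios.

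At 12h, few genes were raised far above the unlesioned pool after nerve crush. Atf3, a transcription factor gene switched on by axon injury, was 3.3-fold higher (log2 1.72, SE 0.29, adjusted p = 0.000307), the monocyte chemokine gene Ccl2 2.56-fold (log2 1.36, SE 0.23, adjusted p = 0.000306) and the growth arrest genes Gadd45g and Gadd45a 2.03-fold and 2-fold. Atf3 was 2.46, 0.012 and 2.70 on the 3 arrays, so replicate 2 lacked its rise. Whether that array is as labelled is not settled, and the results at SN 12h include it. Rtn4 (log2 −1.66, SE 0.17, adjusted p = 2.69e-06), Psap (log2 −1.62) and Cmip (log2 −1.60) were lower than in the pool. Of 4140 genes called, 1606 were higher and 2534 lower, with 8 and 25 at least 2-fold, and median centring gave 560 higher and 10672 lower. Voltage-gated sodium channel genes were the list that passed, 0 higher and 4 lower of 11 (median −0.21, camera adjusted p = 0.0166, adjusted p = 0.659 with an estimated correlation), though not under median centring (adjusted p = 0.0611).

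By 24h after nerve crush Atf3 was 19.7-fold higher than in the pool (log2 4.30, SE 0.29, adjusted p = 3.01e-09), Flrt3 8.51-fold (log2 3.09), Csrp3 8.01-fold (log2 3.00, SE 0.11, adjusted p = 3.54e-13), Gadd45a 7.54-fold (log2 2.92) and Arg1 6.61-fold (log2 2.73). Myelin basic protein transcript Mbp was 2.57-fold lower (log2 −1.36, SE 0.17, adjusted p = 1.65e-05), as were Rsrp1 (log2 −1.47) and Myom3 (log2 −1.34). Of 35 regeneration-associated genes 24 rose and 2 fell (26 and 2 adjusted over the list alone; median 0.69, camera adjusted p = 6.32e-26, adjusted p = 5.69e-05 with an estimated correlation), and the median was 0.43 under median centring. Of 15 immediate-early genes 7 rose (median 0.21, camera adjusted p = 0.00125, adjusted p = 0.194 with an estimated correlation). Of 17 Schwann cell myelin genes 9 fell and 1 rose (11 and 1 adjusted over the list alone; median −0.40, camera adjusted p = 4.72e-05, adjusted p = 0.314 with an estimated correlation). Of 20 extracellular matrix genes 7 fell (median −0.35, camera adjusted p = 0.00336, adjusted p = 0.558 with an estimated correlation). In all 4499 genes were called, 2123 higher and 2376 lower, 59 and 18 of them at least 2-fold, with 601 higher and 5662 lower under median centring.

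At 72h after nerve crush the largest rises were in Crisp3 (40.3-fold, log2 5.33, SE 0.080, adjusted p = 7.69e-21), Csrp3 (32-fold), Atf3 (19.2-fold, log2 4.26), Vip (17.6-fold, log2 4.14, SE 0.10, adjusted p = 4.05e-17) and the C-type lectin gene Reg3b (16.5-fold, log2 4.04, SE 0.21, adjusted p = 1.42e-11). Mbp (log2 −1.24), Gna14 (log2 −1.16) and Ckmt2 (log2 −1.14) fell. Regeneration-associated genes were raised at 72h as well, 28 of 35 rising and 0 falling (29 and 0 adjusted over the list alone; median 1.01, camera adjusted p = 8.25e-29, adjusted p = 2.9e-05 with an estimated correlation). Of 8 neuropeptide genes 6 rose (median 1.31, camera adjusted p = 6.75e-08, adjusted p = 0.0383 with an estimated correlation). Macrophage genes passed from this time on, with 16 of 25 higher and 1 lower (18 and 1 adjusted over the list alone; median 0.64, camera adjusted p = 1.32e-10, adjusted p = 0.124 with an estimated correlation). So did complement genes, with 12 of 17 higher and 1 lower (median 0.55, camera adjusted p = 2.06e-05, adjusted p = 0.238 with an estimated correlation). Oxidative phosphorylation genes leaned down, 12 of 28 lower and 2 higher (median −0.17, camera adjusted p = 0.00035, adjusted p = 0.0432 with an estimated correlation). The 4 positive medians stayed above 0 under median centring, at 0.50, 0.91, 0.25 and 0.14, and the oxidative phosphorylation list also passed there (adjusted p = 0.000357). The count was 6344 genes, 3051 higher and 3293 lower, with 129 and 24 at least 2-fold, and 1154 higher and 10315 lower under median centring.

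At 7d after nerve crush Crisp3 (33.4-fold, log2 5.06), Atf3 (20.5-fold, log2 4.35, SE 0.29, adjusted p = 8.44e-10), Vip (19.8-fold, log2 4.31, SE 0.10, adjusted p = 2.72e-17), Reg3b (16.9-fold, log2 4.08) and Csrp3 (14.9-fold, log2 3.90) were still the most raised. Gap43, the growth cone protein gene, reached 1.74 and Npy 3.12. Rbm38 (log2 −1.46, SE 0.30), Pmp2 (log2 −1.39, SE 0.20), Shisa4 (log2 −1.39) and Mbp (log2 −1.26) fell. Among the 35 regeneration-associated genes 29 rose and 0 fell (30 and 1 adjusted over the list alone; median 0.84, camera adjusted p = 6.29e-30, adjusted p = 2.27e-05 with an estimated correlation). MHC class II genes rose, 5 of 7 (median 1.04, camera adjusted p = 0.000249, adjusted p = 0.0287 with an estimated correlation), with Cd74 at 1.53 and RT1-Da at 1.62. Macrophage genes rose as well, 16 of 25 (18 adjusted over the list alone; median 0.73, camera adjusted p = 2.02e-11, adjusted p = 0.0663 with an estimated correlation). So did 5 of 8 neuropeptide genes (median 1.28, camera adjusted p = 3.16e-08, adjusted p = 0.0217 with an estimated correlation). Of 21 gp130 cytokine and JAK-STAT genes 7 rose and 2 fell (median 0.084, camera adjusted p = 0.00315, adjusted p = 0.0287 with an estimated correlation). These 5 medians stayed positive under median centring, at 0.71, 0.83, 0.56, 1.12 and 0.068. The count was 5530 genes, 2777 higher and 2753 lower, with 122 and 31 at least 2-fold, and 777 higher and 3282 lower under median centring.

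Root crush raised Atf3 already at 12h, 7.57-fold above the pool (log2 2.92, SE 0.29, adjusted p = 5.77e-06). The Fc receptor gene Fcgr2b (3.58-fold, log2 1.84, SE 0.24, adjusted p = 0.000101), the secreted neuronal peptide gene Vgf (3.56-fold, log2 1.83, SE 0.16, adjusted p = 1.33e-06), Ccl2 (3.34-fold, log2 1.74) and Cebpd (2.9-fold, log2 1.54, SE 0.12, adjusted p = 3.41e-07) also rose. Gjb6 (log2 −1.28), Rbm38 (log2 −1.13) and Ptgds (log2 −1.07) fell. Of 15 immediate-early genes, which answer within hours to stimulation, 9 rose and 0 fell (median 0.45, camera adjusted p = 1.28e-08, adjusted p = 0.0094 with an estimated correlation), with Jun at 1.31 and Fos at 0.98. Of 35 regeneration-associated genes 9 rose (13 adjusted over the list alone; median 0.19, camera adjusted p = 3.46e-07, adjusted p = 0.0276 with an estimated correlation), and both medians were higher under median centring, at 0.68 and 0.41. Of 20 neurotrophic genes 4 rose (median 0.21, camera adjusted p = 6.96e-05, adjusted p = 0.0913 with an estimated correlation). Of 26 cholesterol biosynthesis genes 7 rose (median 0.13, camera adjusted p = 0.002, adjusted p = 0.12 with an estimated correlation). In all 2264 genes were called, 1189 higher and 1075 lower (27 and 8 at least 2-fold), with 551 higher and 770 lower from Agilent's own log ratios and 3241 higher and 776 lower under median centring.

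At 24h after root crush Atf3 was 10-fold (log2 3.32, SE 0.29, adjusted p = 4.48e-07), Reg3b 5.77-fold (log2 2.53) and Vgf 3.82-fold (log2 1.93) above the pool, and the related lectin gene Reg3a rose with them (log2 1.67, SE 0.15). The kininogen gene Kng2 was at least 3.06-fold higher (adjusted p = 2.83e-05), not being well above background in the pool. Calb1, a calcium buffer gene, was 2.14-fold lower (log2 −1.10, SE 0.12, adjusted p = 4.18e-06). Of 25 macrophage genes 14 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.35, camera adjusted p = 0.000102, adjusted p = 0.36 with an estimated correlation). Of 17 complement genes 12 rose and 0 fell (median 0.48, camera adjusted p = 0.000102, adjusted p = 0.36 with an estimated correlation). Of the regeneration-associated genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.19, camera adjusted p = 0.000134, adjusted p = 0.167 with an estimated correlation). The large-diameter afferent list leaned down, 5 lower and 2 higher of 16 (median −0.18, camera adjusted p = 0.00606, adjusted p = 0.36 with an estimated correlation), but its median turned to 0.17 under median centring, where neither it (adjusted p = 0.95) nor the macrophage list (adjusted p = 0.0525) passed. The count was 6416 genes, 3451 higher and 2965 lower, with 33 and 5 at least 2-fold, and 11690 higher and 2291 lower under median centring.

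At 72h after root crush Reg3b (10.6-fold, log2 3.40, SE 0.21), Atf3 (6.43-fold, log2 2.69), Reg3a (6.11-fold, log2 2.61), Vgf (5.4-fold, log2 2.43) and Arg1 (2.78-fold, log2 1.48) were raised. Arhgef25 fell 4.73-fold (log2 −2.24, SE 0.16, adjusted p = 2.9e-08). Macrophage genes rose, 19 of 25 higher and 0 lower (20 and 0 adjusted over the list alone; median 0.47, camera adjusted p = 1.56e-06, adjusted p = 0.26 with an estimated correlation). Complement genes rose with them, 14 of 17 (15 adjusted over the list alone; median 0.52, camera adjusted p = 1.78e-05, adjusted p = 0.26 with an estimated correlation). Of the 35 regeneration-associated genes 23 rose and 2 fell (median 0.31, camera adjusted p = 1.56e-06, adjusted p = 0.0752 with an estimated correlation). Peptidergic nociceptor genes leaned up, 5 of 14 (median 0.19, camera adjusted p = 0.0218, adjusted p = 0.33 with an estimated correlation), with Calca at 0.69. Cell cycle genes rose, 9 of 25 with 1 lower (median 0.10, camera adjusted p = 0.00791, adjusted p = 0.33 with an estimated correlation). Schwann cell myelin genes fell, 5 of 17 (median −0.23, camera adjusted p = 0.0218, adjusted p = 0.431 with an estimated correlation), but their median turned to 0.41 under median centring. Neither they (adjusted p = 0.884) nor the peptidergic (adjusted p = 0.064) or cell cycle list (adjusted p = 0.252) passed there. The count was 7210 genes, 3673 higher and 3537 lower, with 31 and 27 at least 2-fold, and 12933 higher and 2552 lower under median centring.

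At 7d after root crush Reg3b (9.96-fold, log2 3.32), Reg3a (5.63-fold, log2 2.49), Vgf (5.52-fold, log2 2.47, SE 0.16, adjusted p = 9e-09), Atf3 (3.5-fold, log2 1.81, SE 0.29, adjusted p = 0.000272) and Npy (3.04-fold, log2 1.60, SE 0.18) were raised. The myelin lipid carrier gene Pmp2 fell 2.46-fold (log2 −1.30), with Myom3 (log2 −1.32), S100a3 (log2 −1.20) and Cfap100 (log2 −1.19). Of 17 Schwann cell myelin genes 11 fell and 0 rose (13 and 0 adjusted over the list alone; median −0.50, camera adjusted p = 9.32e-07, adjusted p = 0.311 with an estimated correlation), but the median turned to 0.10 under median centring. Of 14 peptidergic nociceptor genes 8 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 0.00979, adjusted p = 0.388 with an estimated correlation). Of 13 non-peptidergic genes 6 rose (median 0.26, camera adjusted p = 0.00804, adjusted p = 0.311 with an estimated correlation). Of the regeneration-associated genes 12 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.12, camera adjusted p = 0.00985, adjusted p = 0.376 with an estimated correlation). None of these 4 lists passed under median centring (adjusted p = 0.219, 0.0716, 0.0548 and 0.151). The count was 6019 genes, 3469 higher and 2550 lower, with 18 and 17 at least 2-fold, and 12965 higher and 2217 lower under median centring.

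Set against root crush at 12h, nerve crush left Cmip (4.19-fold lower, log2 −2.07, SE 0.29, adjusted p = 9.78e-05), Psap (4.03-fold lower, log2 −2.01) and Rtn4 (3.39-fold lower, log2 −1.76) below their DR levels, and Fcgr2b with them (log2 −1.84, SE 0.34, adjusted p = 0.00112). Cd44 (2.2-fold higher, log2 1.14, SE 0.21, adjusted p = 0.0011), Gjb6 (2.31-fold, log2 1.21, SE 0.30) and Ptgds (2.32-fold, log2 1.21) were higher. Immediate-early genes were lower in SN at this time, 4 of 15 with 0 higher (6 adjusted over the list alone; median −0.24, camera adjusted p = 0.0016, adjusted p = 0.199 with an estimated correlation). So were 8 of 20 neurotrophic factor and receptor genes (12 adjusted over the list alone; median −0.36, camera adjusted p = 0.000189, adjusted p = 0.199 with an estimated correlation). Under median centring the neurotrophic list still passed (adjusted p = 0.00535) and the immediate-early list did not (adjusted p = 0.0591). In all 3786 genes differed, 1474 higher and 2312 lower in SN (15 and 90 at least 2-fold), with 1023 and 11537 under median centring and 1530 in all when the 6 arrays were fitted alone.

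By 24h Csrp3 (5.93-fold, log2 2.57, SE 0.15, adjusted p = 6.05e-09), Vip (4.03-fold, log2 2.01, SE 0.14), Arg1 (3.81-fold, log2 1.93) and Gadd45a (3.7-fold, log2 1.89) were higher in SN than in DR. The kininogen genes Kng2 (at least 2.57-fold, adjusted p = 0.000609) and Kng1 (at least 2.72-fold, adjusted p = 0.0014) were lower in SN, where neither was well above background. The Schwann cell gene Prx (2.55-fold lower, log2 −1.35, SE 0.22) and the basement membrane gene Nid1 (2.59-fold lower, log2 −1.37) were lower too. In the mean of the 4 times the 3 Nid1 probes ran from −0.43 to −0.012. Regeneration-associated genes were higher, 17 of 35 with 1 lower (22 and 1 adjusted over the list alone; median 0.48, camera adjusted p = 2.32e-10, adjusted p = 0.00943 with an estimated correlation), with a median of −0.21 under median centring, where the list still passed (adjusted p = 0.00657). Extracellular matrix genes were lower, 9 of 20 (11 adjusted over the list alone; median −0.49, camera adjusted p = 0.0015, adjusted p = 0.605 with an estimated correlation). So were 5 of 17 complement genes (7 adjusted over the list alone; median −0.38, camera adjusted p = 0.00616, adjusted p = 0.636 with an estimated correlation). The count was 4512 genes, 2130 higher and 2382 lower, 85 and 43 of them at least 2-fold, with 1710 and 12297 under median centring and 2745 in all when the 6 arrays were fitted alone.

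At 72h Crisp3 was 41.3-fold higher in SN than in DR (log2 5.37, SE 0.11, adjusted p = 7.22e-18), Csrp3 19.7-fold (log2 4.30, SE 0.15), Vip 12.4-fold (log2 3.63, SE 0.14), Gal 7.32-fold (log2 2.87, SE 0.25, adjusted p = 1.7e-07) and Il24 7.3-fold (log2 2.87, SE 0.16). Tnni3k (log2 −1.77, SE 0.33), Gna14 on its brightest probe (log2 −1.47), Gprc5c (log2 −1.45) and Cdkn2a (log2 −1.44) were lower. Among the 35 regeneration-associated genes 21 were higher and 1 lower (22 and 1 adjusted over the list alone; median 0.60, camera adjusted p = 2.6e-11, adjusted p = 0.00617 with an estimated correlation), with a median of −0.11 under median centring. Of 14 peptidergic nociceptor genes 10 were lower and 0 higher (median −0.50, camera adjusted p = 0.000341, adjusted p = 0.217 with an estimated correlation, adjusted p = 0.0545 under median centring). Of 13 non-peptidergic genes 9 were lower (median −0.39, camera adjusted p = 0.000365, adjusted p = 0.115 with an estimated correlation). Neuropeptide genes were higher, 5 of 8 with 1 lower (median 0.43, camera adjusted p = 0.000588, adjusted p = 0.217 with an estimated correlation). The count was 6630 genes, 3306 higher and 3324 lower, 131 and 54 of them at least 2-fold, with 2362 and 13916 under median centring.

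At 7d Vip (15.7-fold, log2 3.97, SE 0.14), Csrp3 (13.9-fold, log2 3.79) and Gal (6.15-fold, log2 2.62, SE 0.25) were higher in SN, with Crisp3 at least 27.7-fold higher (adjusted p = 3.52e-17) and Or8g28c-ps1 at least 6.84-fold (adjusted p = 1.38e-12), neither being well above background in DR. Igf2 (3.09-fold lower, log2 −1.63, SE 0.45, adjusted p = 0.0158), Shisa4 (log2 −1.57), the lymphoid chemokine gene Ccl21 (log2 −1.56) and Gjb6 (log2 −1.54) were lower. Of 35 regeneration-associated genes 24 were higher and 0 lower (26 and 0 adjusted over the list alone; median 0.75, camera adjusted p = 2.05e-22, adjusted p = 0.00014 with an estimated correlation), with a median of 0.12 under median centring. MHC class II genes were higher, 5 of 7 (median 1.05, camera adjusted p = 4.45e-05, adjusted p = 0.0229 with an estimated correlation), also under median centring (0.34). Of 25 macrophage genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 0.000311, adjusted p = 0.524 with an estimated correlation), with a list median of −0.24 under median centring. Of 14 peptidergic nociceptor genes 8 were lower and 1 higher (10 and 1 adjusted over the list alone; median −0.55, camera adjusted p = 0.000311, adjusted p = 0.224 with an estimated correlation). The count was 3939 genes, 1814 higher and 2125 lower, 95 and 44 of them at least 2-fold, with 1625 and 12487 under median centring.

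Across the 4 times 291 genes were called higher in SN at every time and 409 lower at every time, while 200 were called higher at one time and lower at another. The 72h and 7d comparisons shared 1272 higher and 1436 lower genes, but their SN arrays share a scan day and all arrays share the pool, so sharing is no evidence of a lasting lesion effect. Among genes with a symbol 34.3 percent of the calls in the mean comparison were higher in SN, against 58.2 percent among accessions without one.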

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

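The tests below of the regeneration-associated and skeletal muscle lists were chosen only after their results were seen. The others were fixed beforehand. For 1311 genes the difference between SN and DR changed with time, by a test of lesion by time in limma. Of the 49 genes examined for this by the naming rule, 24 were called: Crisp3 (adjusted p = 1.49e-15), Vip (3.59e-10), Or8g28c-ps1 (3.62e-10), Csrp3 (7.47e-10), Ptprh (1.21e-08), Ucn (2.18e-08), Tgm1 (5.91e-08), Il24 (7.53e-08), Sprr1a (7.63e-07), Ankrd1 (1.61e-05), Kcnd3 (0.000392), Npy (0.00121), Jun (0.00122), Gal (0.00166), Gadd45a (0.00192), Gap43 (0.00256), Smad1 (0.00326), Atf3 (0.00368), Flrt3 (0.00719), Nfil3 (0.00938), Calca (0.0108), Adcyap1 (0.0117), Tac1 (0.0267) and Socs3 (0.0317). Under median centring 10 of the 24 kept the call and 14 lost it, among them Kcnd3 (adjusted p = 0.0555), Atf3 (0.0627), Npy (0.104), Gal (0.181), Jun (0.23) and Gap43 (0.23). With Agilent's own ratios Tac1 (0.0658) and Socs3 (0.106) lost it. Or8g28c-ps1, Ptprh, Ucn, Tgm1 and Il24 entered the 49 by their small p-values in this same test, so their calls were fixed by selection. The share of 24 in 49 is therefore no measure of how common such changes are. Among all 22188 genes tested 5.9 percent were called. Of 37 genes outside the 49 that were named at single times, 12 were called. Tgm1, a transglutaminase gene, went from 0.061 at 12h to 2.88 at 7d in SN and from 0.10 to 0.38 in DR, though no SN 12h array had it well above background. Jun was lower in SN at 12h (0.071 against 1.31 in DR) and higher at 7d (1.26 against 0.73), the latter reversed under median centring (−0.45). Chance labelling of the times is excluded: of 100 regroupings of the times within each lesion 1, the real one, reached 1311 and the highest other gave 74. Each regrouping breaks up changes over time shared by both lesions, which widens the spread within groups. The low counts thus cannot tell how many calls shared changes over time would give without an interaction. The regroupings also mix scan days, so differences between days can add to the real count. Within scan days 783 genes changed differently between the lesions from 12h to 24h. Single outlying arrays were not tested as a cause within groups of 3, but with each array left out the count ranged from 781 to 1646.

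The other counts were set against regroupings in the same way. For the mean of SN and DR 1 of 100 regroupings, the real one, reached 10792 and the highest other gave 5120. For time in SN 1 of 100 reached 1665 against 746. For time in DR 1 of 100 reached 2019 against 448. Chance is excluded for these 3, but scan day is not, since the regroupings also mix scan days. SN against DR at a single time allows 10 splits, too few for a share under 0.05: the real split, 1 of the 10, gave 3786, 4512, 6630 and 3939 and the highest other 0, 0, 1 and 0.

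The 10792 genes called between SN and DR may owe much to scan day, since no day holds both lesions. A constant shift of each day cancels in the change from 12h to 24h within days, and over the called genes the median of this change in SN minus DR, signed by their difference, was 0.034 (0.021 to 0.045 with each array left out), which a constant scan-day shift predicts. For the 74 genes at least 2-fold it was 0.39 (0.32 to 0.53). Dimmer Cy5 on the SN arrays would place the calls near background. Of the genes well above background on all arrays 55.8 percent were called (5840 genes), against 42.2 percent of the others (4952 genes). Call rates also depend on how precisely genes are measured, so they cannot exclude dimness as a source. The 5840 calls lie away from background. A lesion effect already complete at 12h would also give a small change within days, so scan day stays open for most of the small differences.

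The higher regeneration-associated genes after nerve crush could also come from scan day or brightness. The median of the list's change from 12h to 24h in SN minus that in DR was 0.74 (0.64 to 0.79 with each array left out), which a constant scan-day shift would hold near 0, so this explanation is excluded for the rise by 24h. Under median centring it was 0.58 (0.37 to 0.77). Dimmer Cy5 on the SN arrays that acts only near background would hold bright members near 0. The 23 members well above background on all arrays had a median of 0.27 between SN and DR (0.25 to 0.31 with each array left out). Dimness of that kind thus does not account for them. This cannot exclude an effect of brightness away from background, since the spike-in slope also differs between the lesions. Division by the spike-in slope, added after seeing the data, raised the list median to 0.47. Under median centring the list medians between SN and DR were −0.13 in the mean, −0.21 at 24h and −0.11 at 72h. That scaling lowers the median of the tested genes to −0.44 in the mean, so the sign of the list medians mostly restates this shift. Against the other genes the list stayed higher there (camera adjusted p = 0.0278, 0.00657 and 0.00422). A stronger injury response and an effect of brightness away from background stay open, and so does scan day for the levels at 72h and 7d.

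Muscle in the pool, which all arrays share, would cancel between SN and DR. Skeletal muscle genes, Tnnc2 and Myl11 among them, may come from muscle picked up with some ganglia. Of 11 measured, 4 were higher and 0 lower in SN (3 and 0 adjusted over the list alone; median 0.86, camera adjusted p = 0.0864). The list passed under median centring (median 0.26, adjusted p = 0.0335), without the filter (adjusted p = 0.0488) and in 4 of 24 fits with 1 array left out, as without DR 12h replicate 3 (adjusted p = 0.0104), and its median was 0.62 without SN 7d replicate 2. Deviations of members from their group means moved together (median r 0.952), which such tissue predicts. Its member Pvalb is also expressed by proprioceptive neurons and shared with the large-diameter afferent list. The list mean per array ranged from −1.35 on DR 72h replicate 2 to 1.78 on SN 12h replicate 3 and 2.08 on SN 7d replicate 2, with 1.55 on DR 12h replicate 3. Its SD within groups was 0.95 against a difference of 0.86 between SN and DR, but spread within groups does not bear on a shift of group means, so scan day stays open beside muscle tissue.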

How the results depend on the processing

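Of the alternatives to the counts, 241 gave values within 1.5 times and 64 did not. Of those to single genes 1574 kept the side of the threshold, 27 lost the call, 8 gained it and 8 reversed. A reversal was counted only where the gene was called in either fit. Of the list tests 1229 kept the side of the threshold, while 8 lost and 14 gained the call. Camera's direction changed only in lists that passed in neither fit, as gp130 and JAK-STAT with Agilent's own ratios. Medians could still change sign, as regeneration-associated (−0.13) under median centring. Crisp3, Csrp3, Vip, Gal, Sprr1a, Flrt3, Cd44, Kcnd3, Calca and P2rx3 kept direction and call in every fit that tested them. Where no cause is given, the cause was not tested.

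Agilent's own ratios gave 1321 genes in DR 12h, 645 over time in DR and 630 in the interaction. Median centring, which leaves brightness-dependent dye bias in place, gave 11232 in SN 12h, 11469 in SN 72h and 4017, 13981, 15485 and 15182 in DR at 12h, 24h, 72h and 7d. It gave 12560, 14007, 16278 and 14112 in SN against DR at the 4 times, 18440 in their mean, 382 over time in SN and 72 in the interaction. It reversed Atf3 (−0.028), Gap43 (−0.52), Adcyap1 (−0.67), Stat3 (−0.79), Smad1 (−0.43) and Aif1 (−0.50). Without a filter 3062 changed over time in DR. Testing only probes well above background on all arrays, thus fewer genes, gave 4170 in SN 72h, 3582 in SN 7d and 1096, 3012, 3108 and 2804 in DR. The same choice gave 2933, 3249 and 2388 in SN against DR at 24h, 72h and 7d, 5779 in the mean, 567 over time in DR, 780 in the interaction and 3 lists of 26. The deposited series table gave 1471 in DR 12h. The mean of all probes turned Stat3 to −0.17, since its 2 probes differ. Fitting 6 arrays alone, with less information on spread, gave 1530 at 12h and 2745 at 24h. Scan day as a block, which leaves out changes between days, gave 409 over time in SN, 1152 over time in DR and 783 in the interaction, and 6843 in the mean as a random block (9526 with lesion alone and no block). An estimated correlation left 1 list. Chosen after seeing the data, array weights gave 8399 in SN 7d, 3376 over time in DR and 2033 in the interaction, the spike-in slope 1222 over time in DR, and the fit without the 12h groups turned Jun to 0.26 (adjusted p = 0.0459).

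With each array left out, so with fewer arrays, counts ranged in SN over 2978 to 3236, 2613 to 3067 (without replicate 1 2613, without 3 2857), 3844 to 4492 (without 2 3844, without 3 3909) and 3101 to 3761 (without 1 3101, without 2 3494). In DR they ranged over 632 to 1173 (without 1, 2 and 3 828, 632 and 1173), 3616 to 5161 (without 2 3662, without 3 3616), 4465 to 5468 (without 3 4465) and 2800 to 4429 (without 2 2800, without 3 3856). In SN against DR they ranged over 2110 to 3435 (without DR replicate 2 2110), 2793 to 4307 (without DR replicate 3 2793), 4983 to 5582 and 2422 to 3607 (without SN replicates 1 and 2 2575 and 2422, without DR replicate 2 2430). They ranged over 10291 to 10830 in the mean, 1258 to 1795 over time in SN, 1329 to 2392 over time in DR (without DR 24h replicate 2 1332, without DR 7d replicate 2 1329), 781 to 1646 in the interaction (without SN 72h replicate 3 862, SN 7d replicate 1 781, DR 12h replicate 2 823) and 5 to 6 lists. The list medians ranged over 0.26 to 0.38 for regeneration-associated, 0.23 to 0.40 for neuropeptide, −0.41 to −0.37 for peptidergic, −0.31 to −0.26 for non-peptidergic and 0.28 to 0.36 for MHC class II genes. A block for replicate number gave 10778 in the mean, and arrays of the same number were not alike (median r 0.016, −0.26 to 0.29). Signal over background limits dim genes most, as Cy5 was dimmer on the SN arrays.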

Other observations

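Beyond the lists that passed, several neuronal genes differed between SN and DR in the mean of the 4 times. Of all genes tested in this comparison 48.6 percent were called, so a count near that share is nothing particular to a list. None of the other 30 lists passed camera there (smallest adjusted p 0.0864, for skeletal muscle). Some passed camera under an alternative: cell cycle (adjusted p = 0.0219) and extracellular matrix (0.0248) without the filter. Under median centring oxidative phosphorylation (0.00566), lymphocyte (0.0335) and cholesterol (0.0471) passed. Without the 12h groups cytoskeleton (0.0161) and cell cycle (0.0161) did. Among 14 calcium channel genes 2 were higher and 4 lower: the gabapentin-binding subunit gene Cacna2d1 was higher in SN (log2 0.81, turning to −0.32 under median centring), reaching 2.31 at 7d (adjusted p = 6.79e-13), while Cacna2d3 (log2 −0.67) and Cacnb3 (log2 −0.58) were lower (list median −0.080, adjusted p = 0.606). Of 42 potassium channel genes 7 were higher, Kcnd3 among them, and 15 lower, with Kcnk4 (log2 −0.53) and Kcnd1 (log2 −0.33) (median −0.055, adjusted p = 0.606). Of 11 sodium channel genes 2 were higher and 4 lower (median −0.016, adjusted p = 0.606). Of 20 opioid, serotonin and GABA receptor genes 8 were higher and 6 lower (median 0.053 but mean −0.017, adjusted p = 0.766), with Htr3a (log2 −0.58) and Gabbr2 (log2 −0.45) lower and Gabra2 (log2 0.39) higher. Of 21 synaptic vesicle genes 2 were higher and 7 lower (median −0.050, adjusted p = 0.778). Of 16 large-diameter afferent genes 3 were higher and 3 lower (median −0.020 but mean 0.087, adjusted p = 0.766). Of 19 cytoskeleton genes 10 were higher and 6 lower (median 0.16, adjusted p = 0.234). Of 20 neurotrophic genes 3 were higher and 9 lower (median −0.20, adjusted p = 0.398), with Ngfr (log2 −0.48) and Fgfr1 (log2 −0.56) lower and Fgf2 (log2 0.53) higher. Of 15 immediate-early genes 4 were higher and 3 lower (median −0.046 but mean 0.029, adjusted p = 0.778). Of 21 gp130 cytokine and JAK-STAT genes 7 were higher and 7 lower (median −0.041 but mean 0.023, adjusted p = 0.766), with Il6r (log2 0.50) higher and Il6st (log2 −0.36) lower.

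Immune, glial and metabolic genes were also called in both directions, in a comparison that called 48.6 percent of all genes tested. The macrophage growth factor gene Csf1 was higher in SN (log2 0.65, turning to −0.027 under median centring), at 1.83 above the pool by 7d (adjusted p = 1.1e-11), among 25 macrophage genes with 8 higher and 5 lower (median 0.094, adjusted p = 0.606). Of 17 complement genes 3 were higher and 8 lower, Cfb (log2 −0.69) and C3 (log2 −0.42) among the latter (median −0.19, adjusted p = 0.299). Of 26 interferon and MHC class I genes 1 was higher and 6 lower (median −0.058, adjusted p = 0.568). Of 10 lymphocyte genes 1 was higher and 2 lower (median 0.029, adjusted p = 0.766). Of 9 neutrophil and mast cell genes 2 were higher and 0 lower (median 0.028, adjusted p = 0.606). Of 17 Schwann cell myelin genes 1 was higher and 4 lower, with Prx (log2 −0.94) and Mbp (log2 −0.89) lower (median −0.058, adjusted p = 0.409). The 2 Mbp probes gave −0.89 and −0.32. Of 13 repair Schwann cell genes 3 were higher and 3 lower (median −0.041, adjusted p = 0.766). Of 15 satellite glia genes 3 were higher and 3 lower (median −0.070 but mean 0.025, adjusted p = 0.955). Of 7 oligodendrocyte and spinal cord genes 2 were higher and 0 lower (median 0.018, adjusted p = 0.766). Of 26 cholesterol genes 2 were higher and 8 lower, Fasn lower (log2 −0.47) and Scd higher (log2 0.64, turning to −0.36 under median centring) (median −0.11, adjusted p = 0.234). Of 28 oxidative phosphorylation genes 5 were higher and 11 lower (median −0.093, adjusted p = 0.314). Of 25 cell cycle genes 2 were higher and 8 lower (median −0.081, adjusted p = 0.14). Of 18 ER stress genes 6 were higher and 4 lower (median 0.045, adjusted p = 0.303). Of 11 heat shock genes 2 were higher and 3 lower (median −0.042, adjusted p = 0.766). Of 20 extracellular matrix genes 0 were higher and 7 lower, Col5a1 (log2 −0.50) and Lox (log2 −0.45) among them (median −0.24, adjusted p = 0.11). Of 10 endothelial genes 2 were higher and 3 lower (median −0.038, adjusted p = 0.606). Of 11 clock genes 1 was higher and 5 lower (median −0.090, adjusted p = 0.314). Of 13 glucocorticoid-responsive genes 3 were higher and 3 lower (median 0.032, adjusted p = 0.734). Of 6 red blood cell genes 0 were higher and 0 lower (median −0.048, adjusted p = 0.95).

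On SN 12h replicate 2 Atf3 stood at 0.012 and Reg3b at 0.014, against 2.46 and 1.11 on replicate 1 and 2.70 and 1.77 on replicate 3. This array had the lowest mean net Cy5 brightness of the 24 (183), though by the median replicate 3 was dimmer. Without it 2978 genes were called in SN 12h, with fewer arrays, and the regeneration-associated median in the mean of SN and DR was 0.38.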
